A study of Mus musculus with 21 samples.

How the data were processed

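Small RNA was measured by sequencing in 21 libraries made from dissected postnatal brain tissue of CD1 mice. Total RNA had been extracted with the miRNeasy kit, fragments of 15 to 50 bp were gel purified after reverse transcription, and the libraries were read on a SOLiD 5500XL machine. The labels give 8 groups: dorsal and lateral subventricular zone (SVZ) at postnatal day 1 (P1) and P6, rostral migratory stream (RMS) at P15 and P28, and olfactory bulb (OB) at P15 and P28. Each SVZ and OB group holds 3 libraries, RMS at P28 holds 2 and RMS at P15 holds 1. Replicates are not stated to be separate animals, so every p-value here measures the spread between these samples. Replicate numbers follow the titles. No pairing between groups is stated, and none was assumed.

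The deposited table holds a score, a normalized read count rounded to whole numbers, for 45633 features in each of the 21 libraries. The submitters' processing notes name Bowtie, DESeq and the mm9 genome without further detail. Ranked from the highest value down, the values of all libraries followed a common distribution times 1 factor per library, as quantile normalization followed by a scaling would give. After division by that factor the coefficient of variation between libraries was 0% at rank 1, 0.00789% at rank 100 and 0.685% at rank 1000. As deposited it was 5.25%, 5.25% and 5.43%. The factor was taken from each library's highest value, so the 0% at rank 1 is fixed by construction. The column totals, 2943373 to 3467000, are therefore not read depths. The depth of each library is unknown, no interval that needs it is given, and count models could not be fitted because whole reads cannot be recovered from these values. A score near 0 cannot be told from absence.

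The table names 1445 microRNA features, of which 1396 were above 0 in at least 1 library. No microRNA name occurred on more than 1 line of the table. Features with a value of at least 10 in at least 3 libraries, whatever their group, were tested: 807, made up of 580 mature forms and 227 hairpins, with 183 of the mature forms being star forms. Hairpin features are written with the prefix pre-mir, and star forms with an asterisk as in the table. Near-identical members of a family may share reads. The table's names were used as they stand. No coordinates are given because the reference annotation at hand is of another mouse genome build than the one the submitters name, and it served only to tell which microRNA genes are neighbours.

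Values were analysed as log2(value + 1), which understates fold changes of features with low values. A linear model with a mean for each of the 8 groups was fitted in limma with a mean-variance trend, which left 13 residual degrees of freedom before moderation, and 11 comparisons were drawn from it. The comparison of OB with RMS used tissue and age as terms, since both tissues were sampled at both ages. The tests of features and of lists were two-sided, and p-values of features were adjusted by the Benjamini-Hochberg method over the tested features of a comparison. A feature passed at an adjusted p under 0.05. The lone RMS library at P15 was assumed to vary like the libraries of the other groups.

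In the comparisons of OB or RMS with SVZ, tissue and age cannot be told apart, because the SVZ was sampled at P1 and P6 and the other tissues at P15 and P28. Comparisons, tests, feature filter, naming rule, 22 microRNA lists and the first set of alternatives below were chosen before the data were examined. Named microRNAs follow this rule. Among features that passed, with a mean of at least 50 in the higher group and libraries that did not overlap between the groups, the 10 largest log2 fold changes in each direction were taken for each comparison. For comparisons over both ages or walls the difference had instead to have the same sign in each stratum. For the interaction of wall and age the 5 smallest adjusted p-values were taken if they passed. From each list up to 4 members with the smallest p were added, together with all members of the miR-200 family, the miR-183 cluster and the miR-7 family.

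The lists were the miR-200 family, the miR-183 cluster, the miR-7 family, the let-7 family, the miR-17 to miR-92 cluster with its paralogs, neuron-enriched microRNAs, miR-9 with miR-92b, the miR-15/16 family, the miR-130 and miR-301 family, the miR-29 family, the miR-181 family, the miR-23/27/24 clusters, the imprinted Dlk1-Dio3 cluster and the intronic Sfmbt2 cluster. The other lists held markers of cells that a dissection could contain: oligodendrocytes, microglia and leukocytes, erythroid cells, endothelial and mural cells, mesenchymal and meningeal cells, choroid plexus and multiciliated cells, Hox cluster microRNAs and muscle. Members were matched on the microRNA number with any arm or copy, so a list counts features rather than genes. Each list was tested with camera from limma against the other features, with a preset correlation of 0.01 between features and again with an estimated correlation, adjusted over the lists of a comparison. Of 242 list tests, 95 passed with the preset value and 6 with the estimate. The camera direction is relative to the other microRNAs, so it can differ from the sign of a list's median.

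Alternatives chosen beforehand were other pseudocounts (0.5 and 5), no filter, a stricter filter of 100, trimmed mean of M-values (TMM) factors and equal totals over the tested features. Others were a fit to only the libraries of a comparison, limma library weights, replicate blocks, and the omission of each replicate in turn. The last was a test over all features of the table, meaning the 11292 features of every RNA class that passed the filter. Further alternatives were chosen after seeing the data: mature forms only, removal of the library factor, values relative to the median microRNA of each library, and the omission of a pair of libraries with an unusual makeup of RNA classes, the first dorsal SVZ replicate at P1 and the second dorsal SVZ replicate at P6. A count was taken as changed when it moved by more than 1.5 times. The procedure was tested on simulated data with known changes. Between the walls it recovered 47.8% of 2-fold, 94% of 4-fold and 100% of 8-fold changes, for the interaction 19.4%, 55.2% and 72.7%, and between the OB ages 35.8%, 61.2% and 92.4%. False calls made up 2.17% to 4.96% of the calls over the comparisons. The simulated values were independent between features, with the same spread in all groups, changes in both directions and no shift in scaling. Where the real data depart from this, these rates need not hold.

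Computation used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with matplotlib 3.10.9 for figures. Features of other RNA classes (tRNA, snoRNA, repeats, piRNA, snRNA, rRNA and unclassified sequences) were left out of the comparisons, since the series is about microRNAs, and are described with the additional observations.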

Results

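Postnatal neurogenesis in the mouse runs from stem cells in the SVZ, beside the lateral ventricles, along the RMS to the OB, where the young neurons settle. The series sampled small RNA along this route in space and in time. It holds 3 libraries each of dorsal and lateral SVZ at P1 and at P6, 1 library of RMS at P15, 2 of RMS at P28, and 3 each of OB at P15 and P28. Values are deposited normalized scores without a unit, and the read depth behind them is unknown. Levels are given as mean ± SD over n libraries, and log2 fold changes as estimate ± SE. MicroRNAs took 67% to 81.6% of a library's total score. Over the 807 tested features the libraries of a group correlated with r of 0.946 to 0.973, and libraries of different groups with r of 0.716 to 0.966. The first principal component held 53.2% of the variance and the second 12.2%.

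**Figure D1:**
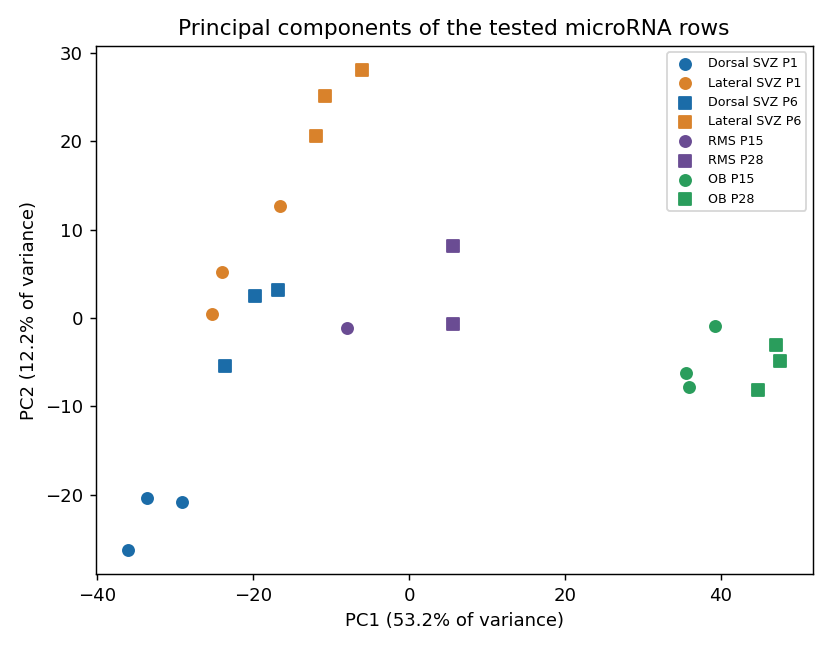
Principal components of log2(value + 1) over the 807 tested microRNA features, with 1 point per library (n = 21). Colours mark dorsal SVZ, lateral SVZ, RMS and OB, with circles for P1 and P15 and squares for P6 and P28. The horizontal axis holds 53.2% and the vertical axis 12.2% of the variance.

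The walls of the SVZ give rise to different kinds of neurons, and the comparison of dorsal with lateral SVZ asked whether their microRNAs differ. The lateral wall held far more of miR-153, a neuronal microRNA, with a level of 2268 ± 328 against 141.2 ± 37.2 in the dorsal wall (n = 6 each). This is 16.2-fold lower in the dorsal wall (log2 fold change -4.02 ± 0.19, adjusted p = 1.75e-13), with all 6 lateral libraries above every dorsal one. MicroRNAs of the imprinted Dlk1-Dio3 cluster, which are transcribed from the maternal chromosome, were lower in the dorsal wall almost throughout. miR-219-3p, abundant in oligodendrocytes, was higher in the dorsal wall by 2.47 ± 0.26 (adjusted p = 1.09e-07), with 4 of 6 dorsal libraries above every lateral one. miR-195, of the miR-15/16 family that restrains the cell cycle, reached 9450 ± 1076 in the dorsal and 3893 ± 937 in the lateral wall (n = 6 each; 1.31 ± 0.15, adjusted p = 3.33e-07, 6 of 6 dorsal libraries above every lateral one).

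Of the Dlk1-Dio3 features, 95 were lower in the dorsal wall and 11 did not pass, and 99 were lower when adjusted over the list alone. Their median log2 fold change was -1.97, and relative to the other microRNAs of each library it was -1.71 ± 0.16. The list test passed with the preset correlation, and its adjusted p with an estimated correlation was 0.038. The level of miR-127 was 676 ± 332 in the dorsal and 3289 ± 715 in the lateral wall (-2.38 ± 0.19), and that of miR-411 was 405.5 ± 75.5 and 2175 ± 407 (-2.42 ± 0.17), each with n = 6 and with all 6 lateral libraries above every dorsal one. Other members with large differences were miR-539-5p (-2.90 ± 0.35, adjusted p = 4.6e-07) and miR-382 (-1.98 ± 0.16, adjusted p = 1.61e-09), with the same separation.

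Many neuron-enriched microRNAs were also lower in the dorsal wall: 24 of 38 features were lower and 14 did not pass, with 25 lower when adjusted over the list alone. The list's median was -1.19, and its call was lost with an estimated correlation (adjusted p = 0.323). miR-218, enriched in motor neurons, showed a log2 fold change of -2.14 ± 0.15, miR-138 -2.35 ± 0.17 and miR-137, which is linked to neuronal maturation, -2.01 ± 0.16, with 6 of 6 lateral libraries above every dorsal one in all 3. In the miR-7 family, 5 of 8 features were lower, as also when adjusted over the list alone, and 3 did not pass (adjusted p = 0.323 with an estimated correlation). miR-7a, known in dopaminergic periglomerular neuron development, showed -2.54 ± 0.19 (adjusted p = 4.9e-10) with levels of 691 ± 156 in the dorsal and 4142 ± 1605 in the lateral wall (n = 6 each). In the miR-130 and miR-301 family 6 of 11 features were lower and 5 did not pass, with 7 lower when adjusted over the list alone, among them miR-301b (-1.79 ± 0.27). That list did not pass as a set (adjusted p = 0.172). The star form miR-218-2*, also of the neuron-enriched list, showed -3.93 ± 0.43 (adjusted p = 1.44e-07) and miR-1247, outside the lists, -3.67 ± 0.48 (adjusted p = 1.53e-06), with all 6 lateral libraries above every dorsal one.

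Fewer lists leaned to the dorsal wall. miR-9*, from the hairpin of the progenitor microRNA miR-9, was higher there, with 51068 ± 17870 against 22985 ± 3978 (n = 6 each) and 6 of 6 dorsal libraries above every lateral one, as were 2 of 8 features of its list, with 2 when adjusted over the list alone (adjusted p = 0.323 with an estimated correlation). In the miR-15/16 family 2 of 20 features were higher and 1 lower, the same when adjusted over the list alone (adjusted p = 0.427 with an estimated correlation), the lower 1 being miR-322 (-0.97 ± 0.20). The let-7 family, which rises as cells differentiate, had 6 of 32 features higher and 1 lower, and 2 higher when adjusted over the list alone (adjusted p = 0.444 with an estimated correlation). miR-23a was higher (0.69 ± 0.14), the single call among 13 features of the miR-23/27/24 clusters (median 0.30, adjusted p = 0.323 with an estimated correlation). Some markers of other cells were higher in the dorsal wall. Of the microglia and leukocyte features 3 of 8 were higher and 5 did not pass, as when adjusted over the list alone (median 0.16, adjusted p = 0.323 with an estimated correlation), and of the erythroid features 1 of 7, as when adjusted over the list alone, a list that did not pass (adjusted p = 0.0715). The hairpin pre-mir-142, of leukocytes and microglia, showed 1.21 ± 0.23 (adjusted p = 0.000233, 6 of 6 dorsal libraries above every lateral one) and the erythroid miR-451 1.01 ± 0.21 (adjusted p = 0.000512, 5 of 6). The tRNA share of the total score was 12.9% ± 3.12 in dorsal and 8.65% ± 2.72 in lateral libraries at P1, and 10.8% ± 0.462 and 5.9% ± 0.6 at P6 (SD, n = 3 each).

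In all, 247 of 807 features differed between the walls, 30 higher and 217 lower in the dorsal wall. The balance depended on scaling: the median log2 fold change over all features was -0.30 as deposited and -0.02 with TMM factors, which moved the split to 111 higher and 185 lower, and values relative to the median microRNA gave 176 higher and 157 lower. Without the pair of libraries of unusual class makeup the count was 240. Lists with medians near 0 turned with the scaling, the miR-17 to miR-92 clusters from -0.01 to 0.31 with TMM factors, the miR-29 family from -0.23 to 0.09 and the miR-181 family from -0.13 to 0.19.

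Taken by age, 14 features were higher and 167 lower in the dorsal wall at P1, and of 164 that differed at P6 22 were higher and the others lower. With TMM factors 34 of 180 calls were higher at P1 and 83 of 203 at P6, and relative to the median microRNA the split was close to even, with 47.5% of 217 calls higher at P1 and 46.4% of 194 at P6. Over all 807 tested features the libraries of both walls did not overlap in 27.1% at P1 and 38.2% at P6, where chance gives 10% with 3 libraries against 3. Both ages shared 109 of the lower calls, where 29.4 would be shared if calls were independent, and 7 of the higher calls (0.382). The tests at both ages used the same estimate of spread for a feature, so part of this sharing is built in. The Dlk1-Dio3 cluster had 87 features lower at P1 and 70 at P6, or 94 and 77 when adjusted over the list alone, with medians of -2.28 and -1.63. Its adjusted p with an estimated correlation was 0.0284 at P1 and 0.13 at P6. At both ages 104 of the cluster's features had negative log2 fold changes, against 302 of the other 701. miR-193b, high in the lateral wall at P1 (4947 ± 730.3 against 626 ± 183.2, n = 3 each), showed -3.02 ± 0.22 there (adjusted p = 1.02e-09), and miR-873 -3.68 ± 0.34 (adjusted p = 6.79e-08). At P6 miR-344 was 8.31-fold lower in the dorsal wall (-3.06 ± 0.26, adjusted p = 1.92e-08) and miR-540-3p showed -3.22 ± 0.49 (adjusted p = 4.32e-05). miR-574-3p was higher in the dorsal wall at P1 (1.94 ± 0.36, adjusted p = 0.000189) and at P6 (1.31 ± 0.36, adjusted p = 0.00982). So was miR-195 at both ages (1.46 ± 0.22 and 1.16 ± 0.22). In each of these cases 3 of 3 libraries of the higher wall lay above all of the lower, as the naming rule required.

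**Figure D2:**
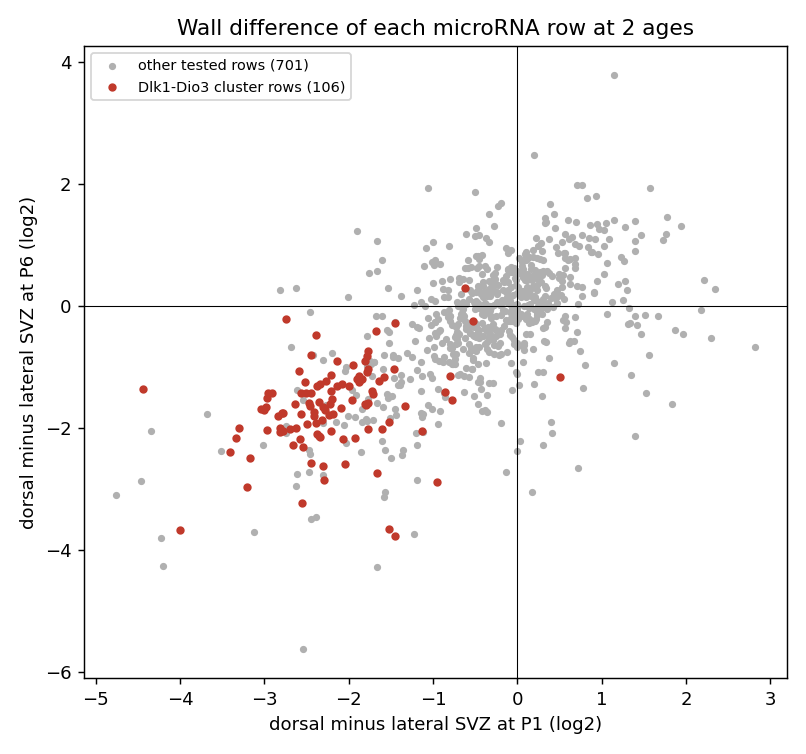
Log2 fold changes of dorsal minus lateral SVZ at P1 (horizontal) and at P6 (vertical) for the 807 tested microRNA features, with the Dlk1-Dio3 features in red and the other 701 in grey. Of the red points, 104 lie below 0 at both ages.

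The comparison of P6 with P1 asked how the SVZ changes over the first postnatal days. miR-34b and miR-34c, which multiciliated cells such as ependyma express strongly, rose. miR-34c went from 296 ± 82.9 at P1 to 5502 ± 1126 at P6 (n = 6 each), an 18.8-fold rise (4.23 ± 0.25, adjusted p = 2.75e-11), and miR-34b-5p and miR-34b-3p rose by 4.14 ± 0.31 and 4.13 ± 0.30. The level of miR-375, a microRNA of endocrine cells, was 16.8 ± 9.39 at P1 and 237.5 ± 50.3 at P6 (3.89 ± 0.40, adjusted p = 1.37e-07). In these 4 all 6 P6 libraries lay above every P1 library. miR-130b fell by 1.51 ± 0.21 on the log2 scale (fold change 2.85, adjusted p = 6.74e-06), with 4 of 6 P1 libraries above every P6 library.

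The list of choroid plexus and multiciliated microRNAs had 14 of 16 features rising and 2 not passing, with 14 when adjusted over the list alone and a median of 2.21. Its call was lost with an estimated correlation (adjusted p = 0.0925). miR-204, of choroid plexus and pigment epithelium, rose by 1.79 ± 0.17. In the miR-29 family, which accumulates in maturing neurons and glia, 8 of 11 features rose and 3 did not pass, as when adjusted over the list alone (adjusted p = 0.208 with an estimated correlation): miR-29a by 1.42 ± 0.13, miR-29b by 1.49 ± 0.14 and miR-29c by 1.35 ± 0.14, with 6 of 6 P6 libraries above every P1 library. Of the neuron-enriched features 23 of 38 rose, 2 fell and 13 did not pass, with 24 and 3 when adjusted over the list alone (adjusted p = 0.484 with an estimated correlation), and miR-128 rose by 1.78 ± 0.22 and miR-129-2-3p by 1.59 ± 0.14. The Dlk1-Dio3 cluster, lower in the dorsal wall, rose with age in 67 features, fell in 1 and did not pass in 38, with 72 and 1 when adjusted over the list alone (median 1.06, adjusted p = 0.37 with an estimated correlation), and with TMM factors 52 rose and 2 fell. miR-666-3p rose by 2.07 ± 0.19 and miR-487b by 1.76 ± 0.17, each with 4 of 6 P6 libraries above every P1 library. Of the oligodendrocyte features 5 of 8 rose, as when adjusted over the list alone (median 0.99), and the list did not pass (adjusted p = 0.207).

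Fewer lists fell. In the miR-17 to miR-92 clusters, known for promoting proliferation, 9 of 33 features fell and 24 did not pass, with 7 when adjusted over the list alone (median -0.40, adjusted p = 0.11 with an estimated correlation). Within them miR-17 fell by 0.78 ± 0.18 on the log2 scale (adjusted p = 0.00133), miR-19b by 0.71 ± 0.17 (adjusted p = 0.00222), each with 5 of 6 P1 libraries above every P6 library, and miR-25 by 0.87 ± 0.16 with 6 of 6. The miR-130 and miR-301 family had 4 of 11 features falling, with 4 when adjusted over the list alone, and 9 with TMM factors (median -0.56, adjusted p = 0.0925 with an estimated correlation). The miR-181 family had 4 of 15 falling, with 4 when adjusted over the list alone, and 8 with TMM factors (median -0.29, adjusted p = 0.0925 with an estimated correlation). Its star form miR-181a-1* fell by 1.23 ± 0.20 (adjusted p = 5.15e-05, 5 of 6 P1 libraries above every P6 library). The miR-15/16 family was mixed, with 4 of 20 features rising and 3 falling, as when adjusted over the list alone, and 2 and 8 with TMM factors (adjusted p = 0.484 with an estimated correlation). miR-16 of this family fell by 0.62 ± 0.14.

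Some markers of other cells rose as well. miR-155 of activated leukocytes rose by 2.12 ± 0.40 (adjusted p = 0.000286, 6 of 6 P6 libraries above every P1 library), with 3 of 8 microglia and leukocyte features rising, as when adjusted over the list alone. In muscle 2 of 3 features rose, as when adjusted over the list alone, among them miR-1 (2.32 ± 0.44, 3 of 6 P6 libraries above every P1 library). Neither list passed as a set (adjusted p = 0.229 and 0.539).

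Over both walls 269 features differed, 242 higher and 27 lower at P6, of which 192 changed at least 2-fold. The median log2 fold change over all features was 0.47 as deposited and 0.19 with TMM factors, with which 72 of 254 calls were lower, and relative to the median microRNA 99 of 282 calls were higher. The dorsal wall had 161 higher and 7 lower features at P6 and the lateral wall 116 higher and 17 lower. With TMM factors these were 147 and 30, and 74 and 46, and relative to the median microRNA most calls were lower at P6, with 41.9% higher in the dorsal and 31.5% in the lateral wall. Over all 807 tested features the libraries of both ages did not overlap in 30% in the dorsal and 33.2% in the lateral wall (10% by chance). The walls shared 76 of the higher calls, where independence gives 23.1, and 4 of the lower (0.147). Here too the tests used the same estimate of spread for a feature, so part of the sharing is built in. The count for the dorsal wall was 90 without the pair of libraries of unusual class makeup, and for the lateral wall it was 61 without lateral P6 replicate 2 and 76 without lateral P1 replicate 3. The counts also depended on how the spread was estimated. A fit to only the dorsal libraries kept 53 of the dorsal calls and lost 115. The same kind of fit in the lateral wall kept 68 and lost 65. In the dorsal wall miR-34c rose by 4.36 ± 0.35 and miR-219-3p by 3.67 ± 0.37 (adjusted p = 3.13e-07), and miR-708 fell by 1.49 ± 0.20 (adjusted p = 9.03e-06). In the lateral wall miR-34c rose by 4.11 ± 0.35 and miR-449a by 2.74 ± 0.40 (adjusted p = 5.91e-05), and miR-25 fell by 1.24 ± 0.22 (adjusted p = 0.000447). Each of these had 3 of 3 libraries of the higher age above all of the lower, as the naming rule required.

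The interaction asked whether the difference between the walls itself differed between P6 and P1. For miR-708 the level was 7268 ± 1183 in the dorsal and 7075 ± 208.5 in the lateral wall at P1, and 2600 ± 510.8 and 11963 ± 1104 at P6 (n = 3 each). The change of the wall difference was -2.24 ± 0.28 (adjusted p = 4.61e-05, and 7.98e-06 to 0.00616 over its alternatives). For miR-219-3p the levels were 83 to 280 in the 3 dorsal libraries and 64.7 ± 22.7 in the lateral wall at P1, and 1771 ± 208 in the dorsal wall and 91 to 163 in the 3 lateral libraries at P6, a change of 2.65 ± 0.53 (adjusted p = 0.0195, and 0.000334 to 0.256 over its alternatives). Its call was lost without dorsal P1 replicate 1 (adjusted p = 0.0587), dorsal P1 replicate 3 (0.0625), lateral P1 replicate 1 (0.0528), lateral P1 replicate 2 (0.0518), dorsal P6 replicate 3 (0.0731) or lateral P6 replicate 1 (0.0873), and in 9 of its 26 alternatives in all. The count of passing features fell to 1 in these omissions except without lateral P1 replicate 2, and without the pair of libraries of unusual class makeup. These were the only features of 807 that passed, while 71 had an unadjusted p under 0.05, and with TMM factors 11 passed, 8 of them positive. The Dlk1-Dio3 cluster had a median of 0.67 with an adjusted p of 0.961 with an estimated correlation.

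**Figure D3:**
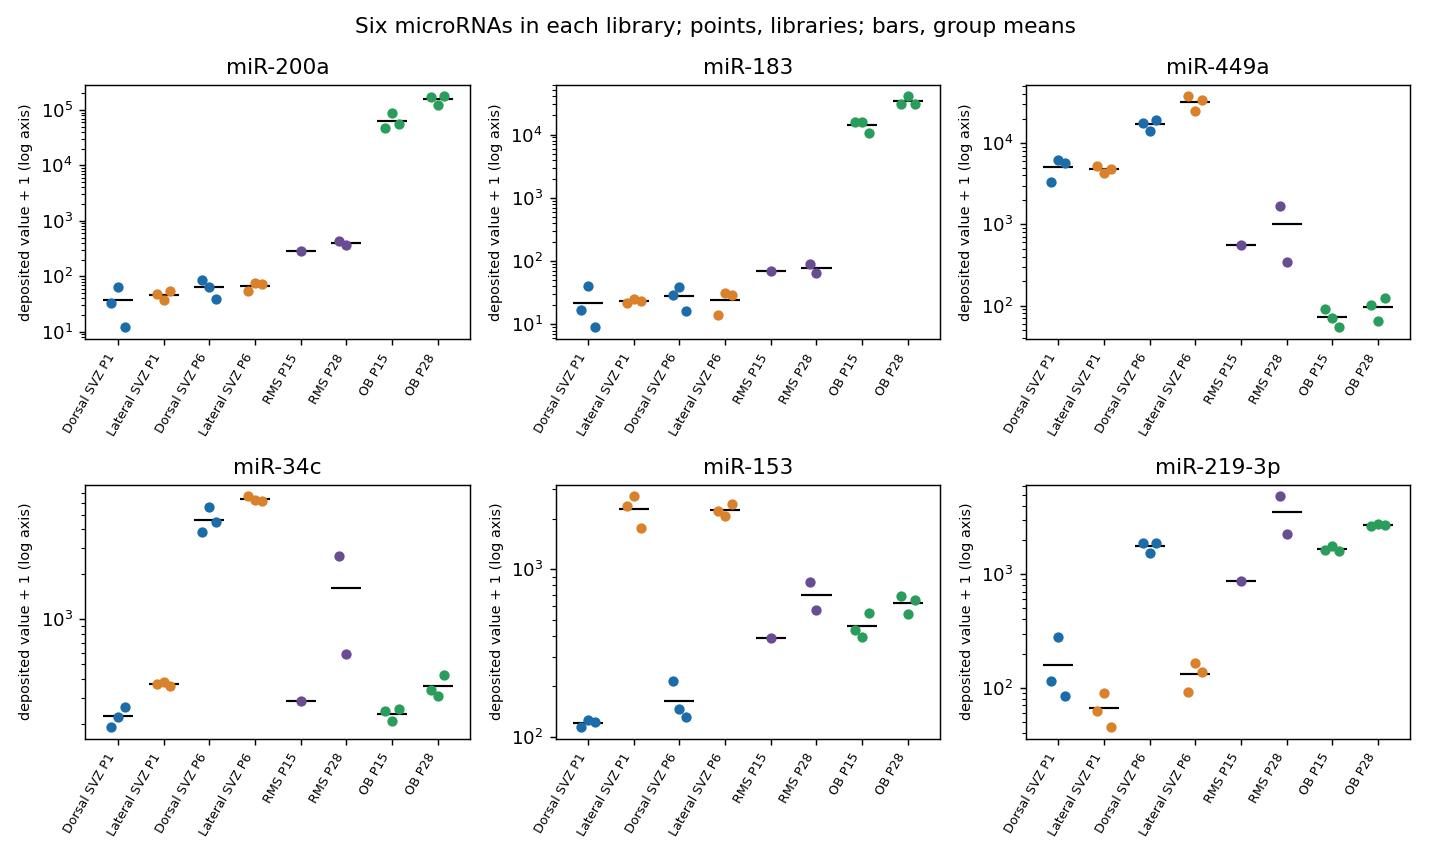
Levels of miR-200a, miR-183, miR-449a, miR-34c, miR-153 and miR-219-3p in each library by group, as deposited value + 1 on a log axis, with points for libraries and bars for group means. miR-200a had a mean of 109990 in OB and 52.4 in SVZ, and miR-449a of 83.3 and 14733.

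From P15 to P28 the comparison within the OB asked about maturation of the bulb. Of the features that passed, miR-29c, of a family that accumulates as neurons mature, rose from 73146 ± 11270 to 234300 ± 64860 (n = 3 each; 1.65 ± 0.19, adjusted p = 1.54e-05), and miR-29b from 14636 ± 3160 to 31714 ± 5414 (1.12 ± 0.20, adjusted p = 0.00472). miR-224 rose from 249 ± 68.7 to 949 ± 26.6 (1.97 ± 0.42, adjusted p = 0.0175), and the clustered miR-27a and miR-23a rose by 1.12 ± 0.23 and 0.95 ± 0.20 (adjusted p = 0.0151 each), while miR-296-3p fell from 234 ± 63 to 87.3 ± 18.2 (-1.40 ± 0.31, adjusted p = 0.0235). In all 6 features the 3 libraries of the higher age lay above all of the other, a condition of the naming rule. Over all 807 tested features the libraries of both ages did not overlap in 31%, where chance gives 10%.

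When adjusted over the list alone, 9 of the 11 miR-29 features rose, against 2 over all features (median 1.16, adjusted p = 0.0858 with an estimated correlation). In the miR-23/27/24 clusters 2 of 13 rose, as when adjusted over the list alone (adjusted p = 0.257 with an estimated correlation). The miR-183 cluster of sensory cells had 5 of 9 features rising when adjusted over the list alone, which did not pass over all features (median 1.59, adjusted p = 0.14 with an estimated correlation), and the miR-130 and miR-301 family 3 of 11 falling when adjusted over the list alone (median -0.54, adjusted p = 0.14 with an estimated correlation). The tRNA share was 14.4% ± 3.14 at P15 and 6.92% ± 1.6 at P28 (SD, n = 3 each).

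In all 6 of 807 features passed, 5 higher and 1 lower at P28, while 115 had an unadjusted p under 0.05. The count depended strongly on how the spread was estimated. A fit to only the OB libraries gave 99, and library weights also gave many more than 6. For age in the dorsal SVZ, a fit to only its own libraries gave 55. The counts from the model of all groups therefore do not show that the OB changed less with age than the SVZ. The split depended on scaling, with 4 higher and 8 lower with TMM factors, 5 and 7 with equal totals, 5 and 2 with the library factor removed and 2 and 1 relative to the median microRNA. The median over all features was 0.21 as deposited and -0.04 with TMM factors. Leaving out OB replicate 1, 2 or 3 at P15 left 3, 1 or 2 features, and leaving out replicate 1 or 2 at P28 left 1 or 2. miR-29c passed in every alternative run. The calls of miR-27a and miR-23a were lost with any of the 6 libraries left out (adjusted p 0.058 to 0.0969 and 0.0589 to 0.0969), miR-23a also with TMM factors (0.0521, with 0.000252 to 0.127 over its alternatives). Those of miR-224 (up to 0.185) and miR-296-3p (up to 0.146) were lost in 5 of 6 omissions, and kept without P15 replicate 1 and without P28 replicate 3 in that order. That of miR-29b was lost without P15 replicate 2 (0.0633) or P28 replicate 1 (0.0778). Over all 20 alternatives the call of miR-29b was lost in 4 (adjusted p up to 0.115) and that of miR-27a in 8. Those of miR-23a were lost in 9, and those of miR-224 and miR-296-3p in 6 each.

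The comparison of OB with RMS asked how the bulb differs from the stream that leads to it. Both are dissected tissues of mixed cells, so a difference need not lie within the migrating young neurons. The largest differences lay in the miR-200 family, known in epithelial and olfactory neuron differentiation, and in the miR-183 cluster of sensory neurons. miR-200a reached 109990 ± 55440 in OB (n = 6) and 362.7 ± 71.7 in RMS (n = 3), a log2 fold change of 8.26 ± 0.37 (adjusted p = 1.13e-14). miR-183 had levels of 23709 ± 11400 and 73.3 ± 13.8 (8.34 ± 0.40, adjusted p = 1.96e-14). All 6 OB libraries lay above every RMS library in both. All 14 features of the miR-200 family and all 9 of the miR-183 cluster were higher in OB, also when adjusted over the list alone, with medians of 8.36 and 8.41, and both lists passed with an estimated correlation (adjusted p = 1.84e-05 and 0.00405).

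Some microRNAs of dividing and progenitor cells were lower in OB. miR-92a had 2543 ± 376.1 in OB and 11040 ± 3850 in RMS (-2.07 ± 0.24, adjusted p = 2.15e-07), and 15 of 33 features of the miR-17 to miR-92 clusters were lower, 1 was higher and 17 did not pass, as when adjusted over the list alone (median -0.92, adjusted p = 0.111 with an estimated correlation). miR-92b, of neural progenitors, had 1478 ± 282 and 5339 ± 1459 (-1.80 ± 0.22), and 4 of 8 features of its list were lower, as when adjusted over the list alone (adjusted p = 0.111 with an estimated correlation). In the miR-181 family 3 of 15 were lower, 9 with TMM factors and 2 when adjusted over the list alone (adjusted p = 0.155 with an estimated correlation), with miR-181a at -0.90 ± 0.19. The multiciliated miR-449a had 83.3 ± 26.3 in OB and 866 ± 728 in RMS (-3.01 ± 0.34, adjusted p = 1.62e-07, 3 of 3 RMS libraries above every OB library), and 6 of 16 features of its list were lower, 1 higher and 9 did not pass, with 7 and 2 when adjusted over the list alone (adjusted p = 0.137 with an estimated correlation).

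Some vessel, connective tissue and other markers were higher in OB. Of the endothelial and mural features 6 of 8 were higher, as when adjusted over the list alone (adjusted p = 0.111 with an estimated correlation), with miR-143 at 2.44 ± 0.28 and miR-145 at 1.55 ± 0.17. All 4 mesenchymal and meningeal features were higher, also when adjusted over the list alone (median 3.13, adjusted p = 0.368 with an estimated correlation). miR-214 had 41 ± 21.9 in OB and 1.67 ± 2.89 in RMS, near the floor. The Hox cluster feature miR-10b (2.80 ± 0.62), miR-1 of muscle (3.25 ± 0.58) and miR-223 of myeloid cells (2.72 ± 0.37) were higher too, with 6 of 6 OB libraries above every RMS library. Their lists had 1 of 1, 2 of 3 and 4 of 8 features higher, as when adjusted over the list alone, and did not pass as sets (adjusted p = 0.311, 0.309 and 0.303), nor did the erythroid list with 3 of 7 (0.309). The repeated Sfmbt2 cluster had 16 of 28 features higher, 19 when adjusted over the list alone (adjusted p = 0.476 with an estimated correlation), with miR-669b at 1.81 ± 0.41. In the miR-130 and miR-301 family 5 of 11 were higher and 1 lower, as when adjusted over the list alone (adjusted p = 0.327), led by miR-301b at 2.45 ± 0.33. The let-7 family had 2 of 32 features higher and 5 lower, 2 and 4 when adjusted over the list alone, a median of 0.15 that turned to -0.27 with TMM factors, and a list test that pointed down (adjusted p = 0.611 with an estimated correlation). let-7b was lower at -0.96 ± 0.18 and let-7c at -1.12 ± 0.20. The Dlk1-Dio3 cluster had a median of 0.49 while its test pointed down (adjusted p = 0.363), with 6 features higher and 2 lower against 13 lower with TMM factors.

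In all 253 of 807 features differed between OB and RMS, 57 lower in OB and the others higher. The count was 176 without the lone RMS library at P15, the lowest over the omissions of 1 library. That library lay at -7.97 on the first principal component, and the RMS libraries at P28 at 5.68 and 5.64. Over all tested features the libraries of OB and RMS did not overlap in 24.9%. The median over all features was 0.55 as deposited and 0.16 with TMM factors, which gave 115 lower of 242, and relative to the median microRNA 79 were higher and 208 lower.

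Between OB and SVZ the miR-200 family and the miR-183 cluster again showed the largest differences. miR-200a had 52.4 ± 20.8 in SVZ (n = 12), and its log2 fold change was 10.98 ± 0.26 (adjusted p = 9.74e-20), and miR-182 showed 9.95 ± 0.26 (adjusted p = 3.92e-19). All 14 and all 9 features of these lists were higher in OB, also when adjusted over the list alone, and both lists passed with an estimated correlation (adjusted p = 0.00146 and 0.0267). The multiciliated miR-449a was far lower in OB, with 14733 ± 12040 in SVZ and 83.3 ± 26.3 in OB (130.4-fold lower, -7.03 ± 0.24, adjusted p = 5.48e-17). In each of these the libraries of the tissues did not overlap, as the naming rule required. Over all 807 tested features they did not overlap in 19.3%.

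Many neuronal microRNAs were higher in OB. miR-132, induced by neuronal activity, had 8580 ± 3355 in OB and 663 ± 538 in SVZ (4.01 ± 0.20, adjusted p = 4.89e-14), and 29 of 38 neuron-enriched features were higher, 2 lower and 7 did not pass, as when adjusted over the list alone (median 1.91, adjusted p = 0.295 with an estimated correlation). All 11 miR-29 features were higher, also when adjusted over the list alone (adjusted p = 0.0837 with an estimated correlation), with miR-29b at 3.27 ± 0.12 and miR-29a at 2.61 ± 0.11. Oligodendrocyte features split into 5 of 8 higher and 2 lower, 5 and 3 when adjusted over the list alone (adjusted p = 0.506), with miR-219-3p at 3.34 ± 0.23 and miR-338-3p at 2.16 ± 0.17. The Dlk1-Dio3 cluster was higher in 75 features and lower in 3, with 28 not passing, as when adjusted over the list alone, with 61 and 5 with TMM factors (median 1.08, adjusted p = 0.486 with an estimated correlation). In the miR-7 family 6 of 8 features were higher, as when adjusted over the list alone and 3 with TMM factors (adjusted p = 0.373), with miR-7b at 1.66 ± 0.24.

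Many proliferation and progenitor microRNAs were lower in OB. miR-17 had 5457 ± 1326 in OB and 33388 ± 11450 in SVZ (-2.58 ± 0.15, adjusted p = 8.1e-13), and 27 of 33 features of its clusters were lower and 6 did not pass, with 28 when adjusted over the list alone (median -1.55, adjusted p = 0.0539 with an estimated correlation). miR-92b showed -2.95 ± 0.14 and miR-9 -1.05 ± 0.20, and 6 of 8 features of their list were lower, as when adjusted over the list alone (adjusted p = 0.0837 with an estimated correlation). The miR-181 family had 9 of 15 lower, as when adjusted over the list alone (adjusted p = 0.0837 with an estimated correlation). The miR-130 and miR-301 family had 7 of 11 lower and 1 higher, 8 and 1 when adjusted over the list alone (adjusted p = 0.176 with an estimated correlation), with miR-130a at -1.63 ± 0.11. In the miR-15/16 family 12 of 20 were lower and 4 higher, as when adjusted over the list alone (adjusted p = 0.295 with an estimated correlation), with miR-15b at -1.28 ± 0.14 and miR-497 at 1.43 ± 0.16. Of the choroid plexus and multiciliated features 13 of 16 were lower and 3 higher, as when adjusted over the list alone (adjusted p = 0.0761 with an estimated correlation). The choroid plexus microRNA miR-204 was among the higher (2.08 ± 0.15). The let-7 family went both ways, with 9 of 32 higher and 7 lower (8 and 7 when adjusted over the list alone), a median of 0.22, a mean of -0.01, a TMM median of -0.12 and a list test that pointed down (adjusted p = 0.0775).

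Some markers of other cells were higher in OB here too: 7 of 8 endothelial and mural features, 4 of 4 mesenchymal and meningeal, 3 of 3 muscle, 5 of 8 microglia and leukocyte and 5 of 7 erythroid features, as when adjusted over each list alone. None of these lists passed as a set (adjusted p of 0.0534, 0.0719, 0.182, 0.314 and 0.456). miR-143 showed 1.42 ± 0.20, miR-1 4.44 ± 0.38 and miR-150 of lymphocytes 2.41 ± 0.17, with all 6 OB libraries above every SVZ library. In all 526 of 807 features differed, 384 of them higher in OB, and 508 with TMM factors, 311 of them higher. Relative to the median microRNA 184 were higher and 307 lower. The median over all features was 0.61 as deposited and 0.31 with TMM factors.

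**Figure D4:**
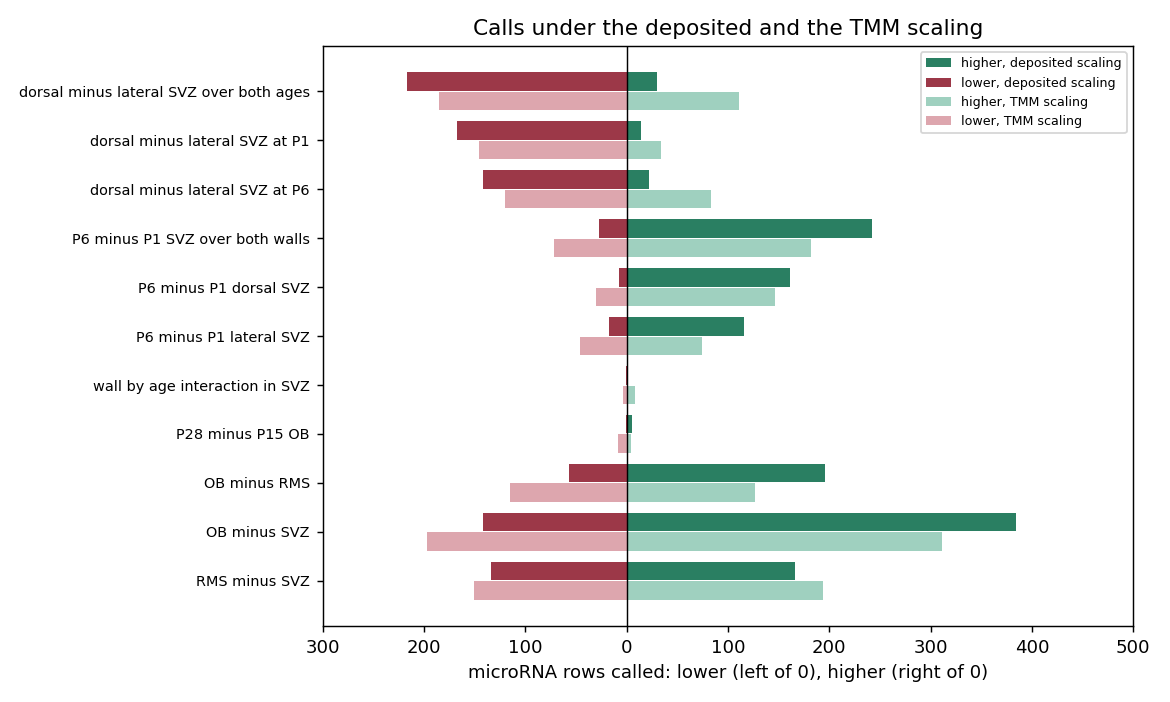
Number of microRNA features called higher (right of 0) and lower (left of 0) in each of the 11 comparisons, as deposited and with TMM factors. OB minus SVZ had 384 higher as deposited and 311 with TMM factors.

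Between RMS and SVZ, miR-132, which neuronal activity induces, and 26 of 38 neuron-enriched features were higher in RMS. miR-132 had 7826 ± 5323 in RMS (n = 3) and 663 ± 538 in SVZ (n = 12), a log2 fold change of 3.63 ± 0.26 (adjusted p = 3.88e-10), its cluster partner miR-212-3p showed 3.79 ± 0.33, and miR-592 showed 4.56 ± 0.55 with 525 ± 229 against 32.3 ± 24.4. All 3 RMS libraries lay above every SVZ library in these, as the naming rule required here and of the lower features that follow. Over all 807 tested features the libraries of RMS and SVZ did not overlap in 8.92%. miR-449a was lower in RMS (-3.94 ± 0.31, adjusted p = 2.55e-09), and so were miR-224 (-3.34 ± 0.33, adjusted p = 7.02e-08) and miR-20b of a miR-17 paralog cluster (-3.69 ± 0.48, adjusted p = 2.75e-06), with all 12 SVZ libraries above every RMS library.

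Of the neuron-enriched features 26 of 38 were higher and 12 did not pass, 27 when adjusted over the list alone (median 1.45, adjusted p = 0.0892 with an estimated correlation). In the miR-29 family 10 of 11 were higher, as when adjusted over the list alone (median 2.01, adjusted p = 0.0649 with an estimated correlation), with miR-29b at 3.11 ± 0.16. All 11 features of the miR-130 and miR-301 family were lower, also when adjusted over the list alone (median -1.50, adjusted p = 0.0649 with an estimated correlation), with miR-130b at -2.40 ± 0.23. In the miR-17 to miR-92 clusters 16 of 33 were lower and 17 did not pass, 19 when adjusted over the list alone (adjusted p = 0.288 with an estimated correlation), with miR-17 at -1.48 ± 0.20. The miR-200 family was higher in RMS than in SVZ in 8 of 14 features, 9 when adjusted over the list alone (median 1.49, adjusted p = 0.0892 with an estimated correlation), with miR-200a at 2.89 ± 0.34 and levels of 362.7 ± 71.7 and 52.4 ± 20.8. The miR-183 cluster had 3 of 9 higher, as when adjusted over the list alone, and did not pass as a set (adjusted p = 0.12). The choroid plexus and multiciliated list had 7 of 16 lower, 2 higher and 7 not passing, 9 and 2 when adjusted over the list alone (adjusted p = 0.288 with an estimated correlation). The Dlk1-Dio3 cluster had 37 features higher, 1 lower and 68 not passing, 36 and 1 when adjusted over the list alone (adjusted p = 0.471 with an estimated correlation), with miR-666-3p at 1.79 ± 0.21, and the Sfmbt2 cluster 10 of 28 lower, 5 when adjusted over the list alone (adjusted p = 0.471 with an estimated correlation). Oligodendrocyte features were 5 of 8 higher and 2 lower, 5 and 3 when adjusted over the list alone (adjusted p = 0.37), with miR-219-3p at 3.33 ± 0.30.

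In all 300 of 807 features differed between RMS and SVZ, 166 of them higher in RMS. With TMM factors 194 of 345 calls were higher, and relative to the median microRNA 50.8% were. The median over all features was 0.05 as deposited and 0.09 with TMM factors. The count was 191 without RMS P28 replicate 2.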

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

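The counts by RNA class, the omission of the pair of libraries with an unusual class makeup and the splits balanced over the walls were tests chosen after the result was seen; the interaction of wall and age was planned.

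The difference between dorsal and lateral SVZ itself changed with age for a pair of microRNAs. For miR-219-3p, a microRNA of oligodendrocytes, the log2 fold change of dorsal over lateral was higher at P6 than at P1 by 2.65. For miR-708 the change was -2.24. Without both libraries of unusual class makeup miR-708 still passed (adjusted p = 0.000833, with 7.98e-06 to 0.00616 over its alternatives), and miR-219-3p did not (adjusted p = 0.0574, with 0.000334 to 0.256 over its alternatives). Its change stayed nearly as large, at 2.61 ± 0.60 against 2.65 ± 0.53 with all libraries, and the call ended with the larger standard error. Of 100 splits of the 12 SVZ libraries within each age, 13 gave at least 2 passing features, the highest of the others 247, which points to a structure of the samples: splits that swap the walls at 1 age carry the whole wall difference into the interaction. These splits therefore decide nothing about chance. With the effects of wall and age removed, and only the 82 splits balanced over the walls, 5 gave at least 2 passing features, the real one included, and the highest other gave 10. Chance is not excluded for that count.

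A pair of SVZ libraries stood apart in their makeup of RNA classes. In dorsal SVZ P6 replicate 2 snoRNA features took 9.42% of the total score, against 3.05% and 2.86% in the other replicates of its group. In dorsal SVZ P1 replicate 1 tRNA features took 16.4% and repeats 6.07%, and microRNAs 67%, the lowest microRNA share of the 21 libraries. The other replicates of its group had tRNA shares of 11.7% and 10.5%, but OB P15 replicate 1 had a higher one (17.2%).

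Features of RNA classes outside the comparisons differed between OB and SVZ by the same test. Of 315 tRNA features tested 180 passed, 55 higher and 125 lower in OB. Among 227 snoRNA features 110 passed, 15 higher and 95 lower. Repeats gave 118 of 829, with 4 higher and 114 lower. For piRNA features it was 26 of 65, 12 higher and 14 lower, and for snRNA 10 of 20, 4 higher and 6 lower. Of 8940 unclassified features 875 passed, 380 of them lower.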

How the results depend on the processing

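The omission of the pair of libraries of unusual class makeup, the fit to mature forms only, the removal of the library factor and the values relative to the median microRNA were tests chosen after the result was seen. Of the calls named by rule 74.9% held in every alternative run. Over all named calls, a test over all features of the table kept 461 and lost 131, values relative to the median microRNA kept 474, lost 100 and turned 18, a fit to only the comparison's libraries kept 506 and lost 86, TMM factors lost 53, and omissions of 1 library kept 6072 and lost 504. List calls were kept in 91 of 95 cases with TMM factors, 87 with mature forms only and 68 with 1 feature per member.

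A test over all features of the table gave 380 for dorsal against lateral SVZ, 66 for age in the lateral wall, 1 for the interaction, 598 for OB against RMS, 1874 for OB against SVZ and 470 for RMS against SVZ, where the number of tested features is larger. Only the comparison's own libraries gave 105 at P1, 55 for age in the dorsal wall and 77 in the lateral wall. They gave 1 for the interaction and 99 for OB age. The spread is then estimated from those libraries alone, and counts fell in the SVZ but rose from 6 for OB age. For the interaction TMM factors gave 11, equal totals 4, removal of the library factor 4 and values relative to the median microRNA 5. For OB age TMM factors and equal totals gave 12 each, a pseudocount of 5 gave 21, no filter 13, the stricter filter 15, library weights 81 and values relative to the median microRNA 3. Without the pair of unusual libraries age in the dorsal wall gave 90, the interaction 1 and OB age 11, where neither library is an OB one. The cause was not tested for any of these changes. Leaving out each library in turn gave 61 to 161 for age in the lateral wall, 1 to 3 for the interaction, 1 to 4 for OB age and 191 to 313 for RMS against SVZ; the lowest of the first came without lateral P6 replicate 2 and of the last without RMS P28 replicate 2. The other 7 counts stayed within 1.5 times in these omissions.

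The sign turned for 18 named calls, all relative to the median microRNA, by whose construction the shift of the median is removed. They were miR-29b (0.12) and miR-181a (0.082) between the walls, miR-29a (0.024) between them at P1, miR-23a (-0.24) with age over both walls and miR-24 (-0.011) in the dorsal wall. Between OB and RMS they were pre-mir-7a-1 (-0.0073), miR-138 (-0.017), miR-29c (-0.018) and miR-29a (-0.22). Between OB and SVZ they were miR-7a-2* (-0.29), miR-7a-1* (-0.52), miR-7b* (-0.23), miR-23b (-0.0057), miR-24 (-0.24), pre-mir-142 (-0.11), miR-126-5p (-0.13), miR-669a-5p (-0.16) and miR-466b-3p (-0.13).

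Numbers in titles and descriptions were checked for pairing: residuals of libraries that share a title number correlated with r above 0.1 in 2 of 21 pairs, and of those that share a description number in 0 of 4 (highest 0.079), so no pairing was used. With the title number as a block the 11 counts stayed within 1.5 times, from 2 for the interaction to 520 for OB against SVZ, and with the description number the walls gave 208, 162 at P1 and 120 at P6. The latter block lost 48 of the 247 wall calls, 40 at P1 and 48 of the 164 at P6, and of the named wall calls it kept 108 and lost 41. Count models were not run because whole reads cannot be recovered, and keeping lines of 1 name apart did not apply. Unknown depth leaves the precision of low scores undefined.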

Other observations

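The tests of scaling for the 3 patterns below, the test of the neuronal share, the test of a common cell source, the test of nasal epithelium and the counts over single hairpins and without forms near the floor were chosen after the result was seen.

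Beyond the microRNAs, tRNA features differed between the walls of the SVZ: 82 of 315 passed, 81 of them higher in the dorsal wall, the side on which the tRNA share of the total was also higher. Of the other classes 7 of 20 snRNA features passed between the walls (5 higher and 2 lower in the dorsal wall), 5 of 65 piRNA (2 and 3), 9 of 227 snoRNA (1 and 8), 5 of 829 repeats (all higher) and 42 of 8940 unclassified features (5 and 37). In the OB from P15 to P28, 5 of 315 tRNA features passed, all of them lower. So did 2 of 20 snRNA features (both lower), 3 of 65 piRNA (1 higher and 2 lower) and 7 of 8940 unclassified (3 and 4). No snoRNA or repeat feature passed.

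The star form and the main form of a microRNA often differed by unequal amounts between OB and SVZ. Of 125 pairs of a star and a main form, 47 (37.6%) had a ratio of star to main form that differed by limma, with 27 star forms gaining and 20 losing against their main form, and 53 at an unadjusted p under 0.05. In 32 of the 125 pairs several hairpins give the same main form, so that a change in which of them is expressed gives a changed ratio too. For miR-135a the star form of one locus, miR-135a-1*, lost against the main form (ratio change -4.52 ± 0.35, adjusted p = 1.73e-08) and that of the other, miR-135a-2*, gained (1.04 ± 0.30, adjusted p = 0.0116). Among the other 93 pairs, whose main form comes from a single hairpin of the table, 32 (34.4%) differed, with 19 star forms gaining and 13 losing. In 13 of these 93 pairs a form had a mean under 10 in 1 of the tissues, where log2(value + 1) caps its fold, so that the ratio can appear to change. Star forms lost in 5 of these 13, among them miR-200a* and miR-182*, both with a mean near 0 in SVZ. Among the 80 pairs without such a form 27 (33.8%) differed, with 19 star forms gaining and 8 losing. For miR-376b of the Dlk1-Dio3 cluster the star form had 365.8 in OB and 130.5 in SVZ and the main form 2007 and 4248 (ratio change 2.80 ± 0.29, adjusted p = 4.23e-07). The star form of miR-17 kept nearer its SVZ level than the main form (ratio change 1.97 ± 0.29, adjusted p = 3.2e-05). For pairs from a single hairpin without a form near the floor, arm use that differs between the tissues is a hypothesis, on which tissue and age cannot be told apart. Reads shared between near-identical family members could also change such a ratio, as could a normalization that acts by rank. Neither was tested.

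MicroRNA genes close on a chromosome may change together between the walls outside the Dlk1-Dio3 cluster as well. Over 31 pairs of neighbours within 10000 bp, from 215 genes with a position, the mean absolute difference of their dorsal minus lateral log2 fold changes was 0.438, against 0.966 over random pairings of the same genes (one-sided permutation p = 1e-04 from 10000 permutations, the smallest they can give). Members of a shared transcript, and near-identical family members that share reads, would both give this.

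The lower level of the Dlk1-Dio3 cluster in the dorsal SVZ was weighed against scaling and cell composition. Relative to the other microRNAs of the same library the cluster's median was still lower in the dorsal wall (-1.71 ± 0.16). This argues against a single scaling factor per library as its cause. A measure of this kind, also used below, cannot test a normalization that acts by rank. Neuron-enriched microRNAs, measured the same way, were lower too (-0.89 ± 0.17), and by less than the cluster (difference -0.86 ± 0.09). A larger share of neurons in the lateral dissections therefore stays open for part or all of it, because the members of both lists are also expressed in other cells. A difference in gene activity between the walls, which the design names, stays open and untested.

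For the rise of miR-34b, miR-34c and miR-449 between P1 and P6, the median relative to the other microRNAs rose by 0.97 ± 0.31. This argues against a single scaling factor per library. More of an unchanged cell source at P6, such as multiciliated ependyma or choroid plexus, would keep their ratio if all of them came from that source. The mean of miR-34b and miR-34c rose over miR-449a by 1.91 ± 0.19 on the log2 scale. This decides nothing about such a source, because miR-449a was already high at P1 (mean 4930, against 242 for the miR-34b and miR-34c features), and a baseline from other cells would give the same shift. A larger share of such cells and a change within cells both stay open.

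For the higher level of the miR-200 family and miR-183 cluster in OB than in RMS, the difference relative to the other microRNAs was 8.42 ± 0.42. A single scaling factor per library is thereby argued against. RNA from multiciliated nasal epithelium, which expresses the miR-200 family, would bring miR-449a along. miR-449a was lower in OB (-3.01 ± 0.34), with a level of 83.3 where miR-200a had 109990. The lower level than in RMS decides nothing by itself, because RMS may hold miR-449a from other cells. Nasal tissue without miR-449a, axons of olfactory sensory neurons, which end in the OB, and a rise within OB cells were not tested and stay open.

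Other splits of the same libraries into groups of equal size were tested for each count. In some comparisons only the real split of those drawn reached the real count. This held for dorsal against lateral SVZ over both ages (1 of 100 splits reached 247, highest other 55.1% of it). It also held for P6 against P1 over both walls (269, highest other 75.8% of it) and OB against RMS (253 in 84 splits, highest other 59). OB against SVZ (526, highest other 239) and RMS against SVZ (300, highest other 100) gave the same. Most other splits mix libraries of unlike groups, which widens the spread, so their low counts (median 0) were partly fixed in advance. Replicates are also not stated to be separate animals, so these splits do not exclude chance. The splits are too few for a share under 0.05 where 3 libraries face 3: dorsal against lateral at P1 (14 higher and 167 lower, highest other 4 in all) and at P6 (164, highest other 2), P6 against P1 in the dorsal wall (168, highest other 2) and in the lateral wall (116 higher and 17 lower, highest other 0), and OB at P28 against P15 (6, highest other 0), with 10 splits each.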
